A study of Mus musculus with 24 samples.

How the data were processed

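Expression was measured in mouse liver RNA on Agilent 4x44K single-colour (Cy3) arrays, 4 per group in 6 groups, on 6 slides of 4 arrays read on 1 day. The extraction protocol mentions liver samples and sorted cells, and which applied to a sample was not stated beyond the liver label. RNA was amplified with WT-Ovation Pico and labelled with BioPrime. Per the file headers, scans were read with Agilent Feature Extraction 10.5.1.1, whereas the submitters' notes give 9.53. The deposited processed signal, and the mean and background signals, are intensities per the file headers. The authors' deposited table holds a signed fold change for each comparison, and the test and normalization behind it are not given in the sources used here. Its false discovery rates and 6 columns of calls were not used here.

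Of 43379 non-control spots per array, those marked by Feature Extraction as outliers (72 to 127 per array) were left out, and repeated probes were averaged (41174 probes). Signals were taken as log2 and divided by each array's 75th percentile (433 to 959.9). Probes well above background on at least 4 of 24 arrays were kept (28051), and the brightest probe stood for its gene, which gave 19290 genes. No spot was saturated. Median signal was 38.4 to 88.9 per array, the spike-in slope 0.923 to 1.03 and the correlation between arrays 0.885 to 0.990. Probe positions are those of the files (mm9), and gene names came from RefSeq accessions.

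Group differences were estimated in R 4.3.3 with limma 3.58.1 and data.table (1.17.8), by a linear model with 6 group means over all 24 arrays and moderated variances, p adjusted by Benjamini-Hochberg within each comparison at 0.05. The comparisons were genotype in untreated females, treated females and treated males, sex in treated wild type and treated dKO, treatment in wild-type and dKO females, and the sex by genotype and genotype by treatment interactions. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

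Gene sets were 33 lists, written before the data were examined like the comparisons and the rule for naming genes. They cover the Foxa genes, Y genes, Xist, male-biased and female-biased liver genes, hormone receptors and the growth hormone axis, CAR, PPARA, NRF2 and p53 targets, and the cell cycle. Further lists cover fetal and tumour genes, hepatocyte, pericentral, periportal, bile acid, fatty acid, cholesterol and circadian genes, and ER stress, interferon, acute phase and immediate early genes. The cell-type lists are biliary, stellate, endothelial, macrophage, T and NK, B and plasma, neutrophil, adipocyte, erythroid and exocrine pancreas. Of these 32 had a set test with camera, at its preset correlation of 0.01 and with the correlation estimated, and with fry.

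Named genes were, per comparison, the 10 highest and 10 lowest log2 fold changes among genes with adjusted p under 0.05, non-overlapping groups (not asked of interactions) and signal above background on all 4 arrays of the higher group. Up to 4 members of each described list were added, as were Foxa1, Foxa2, Foxa3, Esr1, Cyp2b10, Afp, Myc and Il6, and sex-chromosome genes where sex was compared. Some genes that the rule names are not reported here.

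The alternatives tried were the mean of a gene's probes, a fit of only the groups compared, each array left out in turn, normexp background (offset 50), limma's trend and robust options, no filter, a filter on all 24 arrays, array position as a covariate, replicate as a block, slide as a fixed or random block, median centring, quantile normalization and outlier spots kept. After the data were seen, 3 were added: treated dKO females without replicates 2 and 3, treated dKO males without replicates 1 and 4, and only genes bright in a compared group.

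In simulated data with genes changed between treated dKO and wild-type females, 25 of 67 were called at 1.5-fold. The counts were 31 of 67 at 2-fold and 57 of 66 at 4-fold, with 3 unchanged genes called and no wrong sign. They give no false-call rate for the real arrays.

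Across 19269 matched genes, which are not independent replicates, correlation with the authors' signed folds was 0.986 to 0.994 over the comparisons. Of called genes 99.8% to 100% had the same sign.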

Results

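Mouse liver RNA was measured on 24 arrays, 4 in each of 6 groups. The groups were untreated females, treated females and treated males, each either wild type or double knockout (dKO) for the forkhead transcription factors Foxa1 and Foxa2, regulators of hepatocyte genes. Treated mice had received the liver carcinogen diethylnitrosamine (DEN, 20 mg/kg) at 14 to 15 days of age, followed by 8 injections of TCPOBOP (3 mg/kg) 2 weeks apart. TCPOBOP activates the nuclear receptor CAR and promotes liver tumours. The labels call the tissue of all 24 samples liver tumour, untreated ones included, and untreated males were not among the samples. The comparisons addressed how the loss of Foxa1 and Foxa2, the treatment and sex each changed liver gene expression, since the series title places the work in sex differences of liver cancer. Replicates were not stated to come from separate animals, so p-values measure the spread between these samples. Between 50.4% and 68.4% of spots per array were well above background, with a median of 62.4%, and the number of arrays limited the precision. This share averaged 67.2% in treated dKO females and 59.4% to 62.1% in the other groups. Values are log2 fold changes ± SE from 1 limma fit of 19290 genes unless stated. For a gene at background on every array of a group only a bound ("at least") is given, interactions that involve such a group are named here without a size, and "on 2 of 4 wild-type arrays" means that the gene was above background on only those arrays of that group. Gene lists are described by their median log2 fold change, with its range over slides that held both groups ("within slides"), and those described for a comparison were chosen after the list results were seen.

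Foxa1 and Foxa2 signals were low in the groups labelled dKO. Relative to each array's 75th percentile, log2 Foxa1 (probe on chromosome 12, 58641996 to 58642055 of mm9) was -2.30 ± 0.14 (SD) in untreated, -3.15 ± 0.16 in treated female and -2.64 ± 0.39 in treated male wild types. It was not above background on any dKO array. Foxa2 (chromosome 2, 147868698 to 147868757) was 4.45 ± 0.40, 4.01 ± 0.10 and 3.69 ± 0.10 in the same wild-type groups. In dKO it was -3.99 ± 2.22 in untreated females (above background on 3 of 4 arrays), -6.06 ± 0.95 in treated females (2 of 4) and -4.30 ± 1.35 in treated males (2 of 4). Which part of either gene was deleted is not given in the sources used here. The forkhead list of these 3 genes had a median of -2.74 in untreated females, -2.91 in treated females and -2.58 in treated males, dKO over wild type, with Foxa1 at its bound (-1.64, -1.59 and -1.33 with normexp background). Foxa3 (chromosome 7, 19599053 to 19599112), the related factor, was higher in dKO than in wild-type treated males (0.91 ± 0.27, adjusted p = 0.0176). In untreated and treated females its differences of 0.80 ± 0.27 and 0.59 ± 0.27 were not called (adjusted p = 0.0706 and 0.109).

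**Figure D1:**
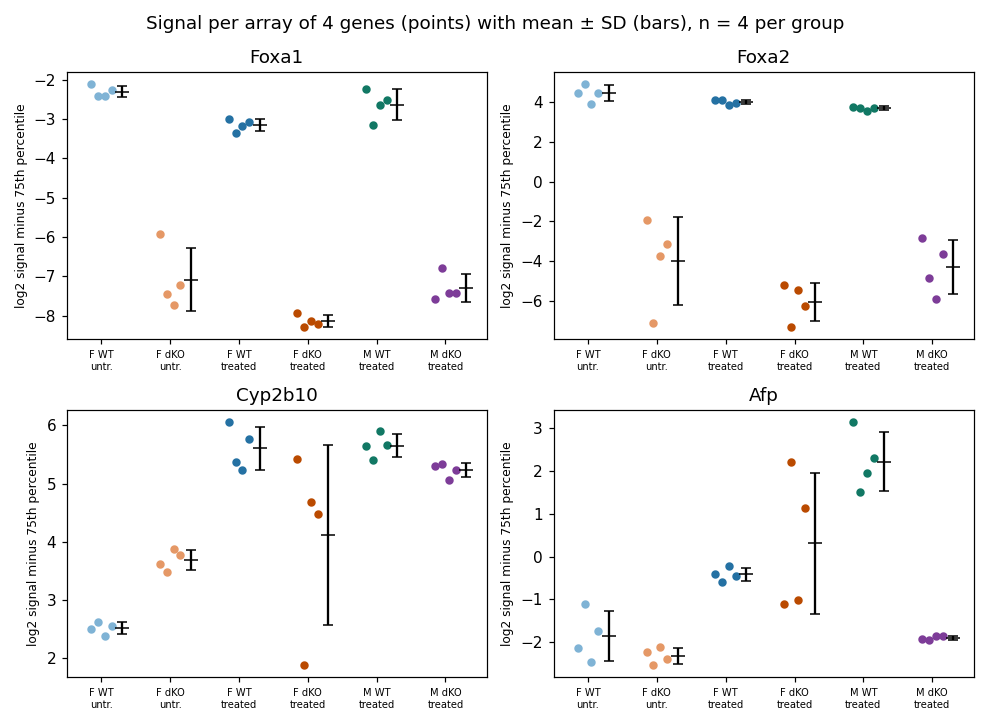
Log2 signal relative to each array's 75th percentile of Foxa1, Foxa2, Cyp2b10 and Afp, with 1 point per array and bars for the group mean ± SD (n = 4). Foxa1 and Foxa2 lay lower on all dKO arrays than on the wild-type arrays, and Afp averaged 2.22 ± 0.69 in treated wild-type males against -1.90 ± 0.05 in treated dKO males.

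**Figure D2:**
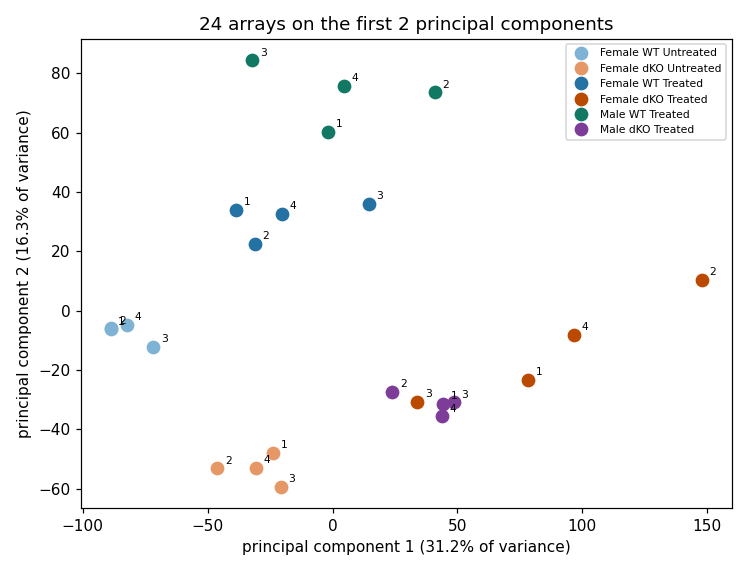
Positions of the 24 arrays on the first and second principal components of the kept probes without missing values, which held 31.2% and 16.3% of the variance, with 1 point per array coloured by group. Treated dKO female replicates 2 and 3 lay farthest from their group mean (root mean square deviation 0.643 and 0.574 in log2).

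Without treatment, genes of several kinds differed between dKO and wild-type female livers. Krt20, a keratin of gut epithelium, was at least 159.6-fold higher, and the bile duct keratin Krt7 rose by 4.44 ± 0.45. Scd2, a desaturase abundant in fetal liver, rose by 6.54 ± 0.35, and the estrogen sulfotransferase Sult1e1 by 7.91 ± 0.67. Acot1, an acyl-CoA thioesterase induced by PPARA, changed by -5.67 ± 0.28, and the glycolate oxidase Hao1 by -6.13 ± 0.45. The organic anion transporter Slco1a1, male-biased in mouse liver, was at least 138-fold lower (largest adjusted p of these 4.85e-06).

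In this comparison 1873 of 19290 genes differed, 993 higher and 880 lower in dKO, 570 and 244 of them by 2-fold or more. Other genes with the largest rises were Mybpc2 (at least 27.2-fold higher), Tinag (at least 23.0-fold higher), Cdh16 (6.09 ± 0.64, on 2 of 4 wild-type arrays), Dnase1 (5.99 ± 0.45, on 1 of 4 wild-type arrays), Fam81a (4.85 ± 0.38, on 2 of 4 wild-type arrays), Spink1 (6.20 ± 0.79, on 3 of 4 wild-type arrays) and Cyp4a12a (6.57 ± 0.71). The largest falls also held Foxa2 (-8.44 ± 0.77, on 3 of 4 dKO arrays), Nlrp12 (-7.27 ± 1.04, on 2 of 4 dKO arrays), Irx1 (at least 26.3-fold lower), Hsd3b5 (at least 27.5-fold lower), Dsg1c (at least 28.4-fold lower), Elovl3 (-5.46 ± 0.61, on 1 of 4 dKO arrays) and Foxa1 (at least 6.68-fold lower). Of these 14 genes Hsd3b5 had the largest adjusted p (0.000372). Cyp2b10 (1.17 ± 0.45), Esr1 (0.53 ± 0.24), Afp (-0.45 ± 0.52), Myc (-0.01 ± 0.25) and Il6 (0.26 ± 0.41, on 1 of 4 dKO arrays and 1 of 4 wild-type arrays) were not called.

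Among bile duct cell markers, 13 of 24 measured were higher, 1 lower, 10 not called (18 and 1 adjusted over the list alone), with Cd24a (3.11 ± 0.41) and Wfdc2 (2.76 ± 0.48) beside Krt7. Its median was 1.30 (1.08 with dim members at their bound, 0.53 with normexp background, 1.01 to 1.47 within slides, camera adjusted p = 4.68e-13, adjusted p = 0.0642 with an estimated correlation). Of the genes of fetal liver and liver tumours, 8 of 27 measured were higher, 1 lower, 18 not called (10 and 1 adjusted over the list alone), led by Scd2, Spink1 (6.20 ± 0.79) and Sox4 (3.35 ± 0.29, on 3 of 4 wild-type arrays). Its median was 0.70 (0.61 with dim members at their bound, 0.30 with normexp background, 0.23 to 0.62 within slides, camera adjusted p = 1.96e-06, adjusted p = 0.133 with an estimated correlation). Of the genes of stellate cells, fibroblasts and matrix, 10 of 29 measured were higher, 0 lower, 19 not called (14 and 1 adjusted over the list alone), such as Loxl1 (1.57 ± 0.29) and Fbln2 (1.72 ± 0.28). Its median was 0.62 (0.38 with slide as a fixed block, 0.33 to 1.09 within slides, camera adjusted p = 1.95e-07, adjusted p = 0.282 with an estimated correlation).

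For macrophages 4 of 20 measured were higher, 0 lower, 16 not called (15 and 0 adjusted over the list alone), Mpeg1 (1.60 ± 0.29) among them. Its median was 1.07 (0.99 with dim members at their bound, 0.80 to 1.46 within slides, camera adjusted p = 1.32e-07, adjusted p = 0.203 with an estimated correlation). Of adipocyte markers, 2 of 7 measured were higher, 0 lower, 5 not called (4 and 0 adjusted over the list alone), Cidea (at least 13.2-fold higher) and Cfd (5.31 ± 1.41, on 3 of 4 dKO arrays and 1 of 4 wild-type arrays). Its median was 2.84 (1.57 with dim members at their bound, 0.66 with normexp background, 0.58 to 3.23 within slides, camera adjusted p = 0.000142, adjusted p = 0.167 with an estimated correlation).

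PPARA targets, genes of fatty acid oxidation, were lower. Here 0 of 26 measured were higher, 10 lower, 16 not called (0 and 15 adjusted over the list alone), with Acot2 (-1.67 ± 0.26) and Cyp4a14 (-3.19 ± 0.57) beside Acot1. Its median was -0.47 (-0.90 to -0.67 within slides, camera adjusted p = 2.44e-07, adjusted p = 0.167 with an estimated correlation). In bile acid synthesis and transport 0 of 25 measured were higher, 4 lower, 21 not called (0 and 4 adjusted over the list alone), Cyp27a1 (-1.48 ± 0.31) and Cyp7b1 (-1.54 ± 0.25) included. Its median was -0.22 (-0.07 with quantile normalization, -0.39 to -0.29 within slides, camera adjusted p = 0.0131, adjusted p = 0.572 with an estimated correlation). In the cell-cycle list 0 of 37 measured were higher, 1 lower, 36 not called (0 and 0 adjusted over the list alone), the one being Ccne2 (at least 1.23-fold lower, on 2 of 4 wild-type arrays). Its median was -0.01 (0 with dim members at their bound, mean 0.01, -0.05 to 0.26 within slides, camera adjusted p = 0.601, adjusted p = 0.940 with an estimated correlation). The bile acid call was lost with the filter on all 24 arrays and with quantile normalization.

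For untreated females calls lost included Ccne2 with slide as a fixed block, Ccne2 and Cfd with normexp background, and Ccne2 and Cfd without some single array. Of 52 called genes followed, the call was lost for 13 with normexp background, 11 with slide as a fixed block, 10 with array position as a covariate and 7 with no filter on dim probes (alternatives that lost 10% or more, single arrays left out apart). The count was 1189 with slide as a fixed block, 730 with normexp background, 2812 with only these 8 arrays in the fit and 1121 to 1774 with 1 array left out.

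After DEN and TCPOBOP, dKO and wild-type females were compared. The mitotic regulators Prc1 (2.54 ± 0.45) and Cdk1 (2.60 ± 0.53) rose, as did the fetal growth factor Igf2 (4.42 ± 0.71) and the collagen Col1a1 (3.35 ± 0.43). Krt20 rose by 7.72 ± 0.85 (on 2 of 4 wild-type arrays) and the lipid droplet gene Cidea by 6.56 ± 0.52. The transporter Slc22a28, female-biased in mouse liver, changed by -3.11 ± 0.29, and the pericentral glutamate transporter Slc1a2 by -4.56 ± 0.57. The largest adjusted p of these was 0.00116.

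With 5735 genes called, 2577 higher and 3158 lower in dKO, 1422 rose and 718 fell by 2-fold or more. The largest rises also held Tinag (at least 36.6-fold higher), Slc7a11 (at least 24.7-fold higher), Dnase1 (at least 12.3-fold higher), Wnt10a (at least 19.3-fold higher), Tmem145 (at least 18.8-fold higher), Mybpc2 (5.41 ± 0.52, on 1 of 4 wild-type arrays), Mgst2 (5.35 ± 0.53) and Chrdl2 (at least 16.9-fold higher). The largest falls held Foxa2 (-10.07 ± 0.77, on 2 of 4 dKO arrays), Pnliprp1 (-9.27 ± 0.66, on 3 of 4 dKO arrays), Slco1a1 (-7.46 ± 0.95, on 2 of 4 dKO arrays), Duoxa1 (at least 13.7-fold lower), Cyp4a14 (-5.74 ± 0.57), Foxa1 (at least 7.52-fold lower), Dlgap1 (at least 6.46-fold lower) and Cfd (-4.87 ± 1.41, on 1 of 4 dKO arrays), whose adjusted p of 0.0139 was the largest of these 16 genes. Myc was higher (1.04 ± 0.25, adjusted p = 0.00434). Cyp2b10, the classic CAR target, was lower (-1.49 ± 0.45, adjusted p = 0.0165). Its value was -0.75 without dKO replicate 2, with the call kept, and the call was lost without wild-type replicate 1. Afp (0.72 ± 0.52), Esr1 (-0.28 ± 0.24) and Il6 (-0.19 ± 0.41, on 2 of 4 wild-type arrays) were not called.

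Of the cell-cycle genes, 33 of 37 measured were higher, 1 lower, 3 not called (34 and 1 adjusted over the list alone), Ccnb1 (2.78 ± 0.62, on 2 of 4 wild-type arrays) and Tpx2 (2.53 ± 0.59, on 2 of 4 wild-type arrays) among the risers. Its median was 1.87 (0.97 with normexp background, 2.49 to 2.65 within slides, camera adjusted p = 3.11e-15, adjusted p = 0.289 with an estimated correlation). The shared slides held dKO replicates 2 and 4. This list averaged 2.10 and 1.38 there, against 0.74 and -0.03 on replicates 1 and 3. Spike-in slopes ran inversely, at 0.923, 0.946, 0.953 and 0.985 on replicates 2, 4, 1 and 3 (other groups averaged 0.989 to 1.02). Any effect of this was not tested. For stellate cell, fibroblast and matrix genes 24 of 29 measured were higher, 0 lower, 5 not called (25 and 0 adjusted over the list alone), Loxl1 (2.73 ± 0.29) and Mmp2 (2.78 ± 0.32) included. Its median was 1.56 (1.505 with dim members at their bound, 1.93 to 1.96 within slides, camera adjusted p = 2.84e-15, adjusted p = 0.126 with an estimated correlation). Bile duct cell markers showed a like direction, as 17 of 24 measured were higher, 1 lower, 6 not called (18 and 1 adjusted over the list alone), Krt7 (4.41 ± 0.45), Cd24a (3.69 ± 0.41) and Ggt1 (4.14 ± 0.55, on 2 of 4 wild-type arrays) among them. Its median was 1.86 (1.47 with dim members at their bound, 0.65 with normexp background, 0.86 to 2.26 within slides, camera adjusted p = 2.86e-11, adjusted p = 0.126 with an estimated correlation).

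Among CAR targets 0 of 29 measured were higher, 15 lower, 14 not called (0 and 19 adjusted over the list alone), Cyp2c55 (-3.86 ± 0.61) and Akr1b7 (-3.19 ± 0.56) included. Its median was -0.88 (-1.71 to -0.86 within slides, camera adjusted p = 7.77e-06, adjusted p = 0.299 with an estimated correlation). For pericentral genes that depend on Wnt signalling 0 of 18 measured were higher, 12 lower, 6 not called (0 and 13 adjusted over the list alone), Sp5 (-2.74 ± 0.51) and Cyp1a2 (-2.16 ± 0.42) beside Slc1a2. Its median was -1.36 (-3.26 to -0.86 within slides, camera adjusted p = 2.29e-05, adjusted p = 0.524 with an estimated correlation). Of female-biased liver genes 0 of 29 measured were higher, 14 lower, 15 not called (0 and 15 adjusted over the list alone), Hao2 (-3.30 ± 0.61) beside Slc22a28. Its median was -1.20 (-2.51 to -1.12 within slides, camera adjusted p = 0.000118, adjusted p = 0.524 with an estimated correlation).

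Secreted and metabolic hepatocyte genes also tended downward, as 0 of 33 measured were higher, 13 lower, 20 not called (0 and 20 adjusted over the list alone), Apoa1 (-1.30 ± 0.36) and the urea cycle enzyme Otc (-1.75 ± 0.53) included. Its median was -0.51 (-1.40 to -0.49 within slides, camera adjusted p = 0.000118, adjusted p = 0.580 with an estimated correlation). Normexp background ended that call. Without dKO replicate 2 the medians were -0.54 (CAR targets), -0.66 (pericentral), -0.58 (female-biased) and -0.23 (hepatocyte genes), with the calls kept. For treated females calls lost included Ccnb1 and Tpx2 with normexp background, and Cfd and Cyp2b10 without some single array. Of 63 called genes followed, the call was lost for 54 with array position as a covariate and 15 with only the groups compared. The count was 5448 with slide as a fixed block, 43 with array position as a covariate and 2128 with only these 8 arrays. Normexp background gave 1739 higher and 5460 lower (median of all genes -0.24 instead of -0.07).

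In treated males dKO was compared with wild type. Krt7 rose by 5.89 ± 0.45 and the epithelial adhesion molecule Epcam by 4.17 ± 0.47 (on 2 of 4 wild-type arrays). Afp, the alpha-fetoprotein of fetal liver and liver tumours, changed by -4.12 ± 0.52, and the mitotic activator Cdc20 changed by -2.98 ± 0.45. The elongase Elovl3, male-biased in mouse liver, changed by -7.87 ± 0.61 (on 2 of 4 dKO arrays), the fatty acid hydroxylase Cyp4a14 by -5.93 ± 0.57 and the aldo-keto reductase Akr1b7 by -5.77 ± 0.56 (largest adjusted p of these 6.08e-05).

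Here 4854 genes differed, 2766 higher and 2088 lower in dKO, 1211 and 676 by 2-fold or more. Further large rises were Cdh16 (7.85 ± 0.64, on 1 of 4 wild-type arrays), Mybpc2 (at least 43.2-fold higher), Wnt10a (at least 45.3-fold higher), Chrdl2 (6.22 ± 0.47, on 1 of 4 wild-type arrays), Ppp2r2b (at least 19.2-fold higher), Scin (at least 23.5-fold higher), Foxj1 (at least 20.6-fold higher), Cpxm2 (at least 20.1-fold higher) and Dkk2 (at least 6.71-fold higher). Further large falls were Pnliprp1 (-9.30 ± 0.66, on 3 of 4 dKO arrays), Duoxa1 (at least 78.0-fold lower), Foxa2 (-7.99 ± 0.77, on 2 of 4 dKO arrays), Krt4 (at least 36.3-fold lower), Meig1 (-6.81 ± 0.65), Npc1l1 (at least 18.2-fold lower) and Atp2b2 (-5.29 ± 0.53, on 3 of 4 dKO arrays), and Foxa1 was at least 5.98-fold lower. The largest adjusted p of these 17 genes was 3.98e-06. Myc was lower (-0.74 ± 0.25, adjusted p = 0.0342). Cyp2b10 (-0.42 ± 0.45), Esr1 (-0.08 ± 0.24) and Il6 (-0.64 ± 0.41, on 1 of 4 dKO arrays and 2 of 4 wild-type arrays) were not called. CAR targets had a median of -0.43 (-0.67 to -0.08 within slides), against -0.88 in treated females.

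For stellate cell, fibroblast and matrix genes 11 of 29 measured were higher, 0 lower, 18 not called (13 and 0 adjusted over the list alone), Mgp (2.94 ± 0.24) and Mmp2 (3.05 ± 0.32) included. Its median was 0.69 (0.43 without treated wild-type male replicate 3, 0.23 to 1.71 within slides, camera adjusted p = 2.00e-06, adjusted p = 0.312 with an estimated correlation). For bile duct cell markers 17 of 24 measured were higher, 2 lower, 5 not called (18 and 2 adjusted over the list alone), Krt23 (4.17 ± 0.34) and Cldn7 (3.68 ± 0.30) beside Krt7. Its median was 2.18 (1.73 with dim members at their bound, 0.59 with normexp background, 1.04 to 2.49 within slides, camera adjusted p = 1.05e-09, adjusted p = 0.225 with an estimated correlation). Of periportal genes 5 of 14 measured were higher, 0 lower, 9 not called (6 and 0 adjusted over the list alone), Igf1 (1.23 ± 0.19) and Cyp2f2 (1.102 ± 0.25) among them. Its median was 0.99 (0.34 to 1.246 within slides, camera adjusted p = 0.00368, adjusted p = 0.537 with an estimated correlation). Pericentral genes moved the other way, as 0 of 18 measured were higher, 14 lower, 4 not called (0 and 15 adjusted over the list alone), with Rhbg (-2.96 ± 0.52) and Slc13a3 (-2.49 ± 0.37). Its median was -1.61 (-1.53 with dim members at their bound, -1.96 to -1.55 within slides, camera adjusted p = 5.10e-09, adjusted p = 0.266 with an estimated correlation).

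Of the cell-cycle genes 0 of 37 measured were higher, 22 lower, 15 not called (0 and 25 adjusted over the list alone), Ccnb1 (-2.64 ± 0.62, on 3 of 4 dKO arrays) and the transcription factor Foxm1 (-2.27 ± 0.41) included. Its median was -1.22 (-1.20 with dim members at their bound, -0.78 with normexp background, -1.82 to -0.72 within slides, camera adjusted p = 5.95e-09, adjusted p = 0.312 with an estimated correlation). Targets of NRF2, the regulator of oxidative stress defence, were lower, as 0 of 22 measured were higher, 12 lower, 10 not called (0 and 13 adjusted over the list alone), with Gsta2 (-3.27 ± 0.69) and the efflux pump Abcc4 (-3.64 ± 0.42). Its median was -1.51 (-1.37 with dim members at their bound, -1.60 to -0.94 within slides, camera adjusted p = 1.05e-09, adjusted p = 0.266 with an estimated correlation). For cholesterol synthesis 0 of 21 measured were higher, 16 lower, 5 not called (0 and 16 adjusted over the list alone), Hsd17b7 (-1.44 ± 0.18) and Mvd (-1.495 ± 0.29) among them. Its median was -1.02 (-1.096 to -0.88 within slides, camera adjusted p = 1.05e-09, adjusted p = 0.266 with an estimated correlation). For fatty acid synthesis 0 of 19 measured were higher, 10 lower, 9 not called (0 and 12 adjusted over the list alone), Acacb (-2.75 ± 0.48) and Elovl6 (-1.99 ± 0.38) among them. Its median was -0.90 (-1.20 to -0.77 within slides, camera adjusted p = 7.03e-06, adjusted p = 0.266 with an estimated correlation).

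PPARA targets were lower as well: 0 of 26 measured were higher, 10 lower, 16 not called (0 and 10 adjusted over the list alone), Acot1 (-3.98 ± 0.28) and Cyp4a10 (-3.84 ± 0.28) beside Cyp4a14. Its median was -0.52 (-0.87 to -0.18 within slides, camera adjusted p = 2.00e-06, adjusted p = 0.266 with an estimated correlation). With array position as a covariate that median was 0.01 (adjusted p = 0.0408).

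For treated males calls lost included Myc with slide as a fixed block, and Myc without some single array. Of 67 called genes followed, the call was lost for 42 with array position as a covariate. The count was 4909 with slide as a fixed block, 202 with array position as a covariate, 2552 with normexp background and 2676 without dKO replicates 1 and 4, which held trace Xist signal, and median centring turned the balance to 1781 higher and 3024 lower (median of all genes -0.09 instead of 0.04).

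**Figure D3:**
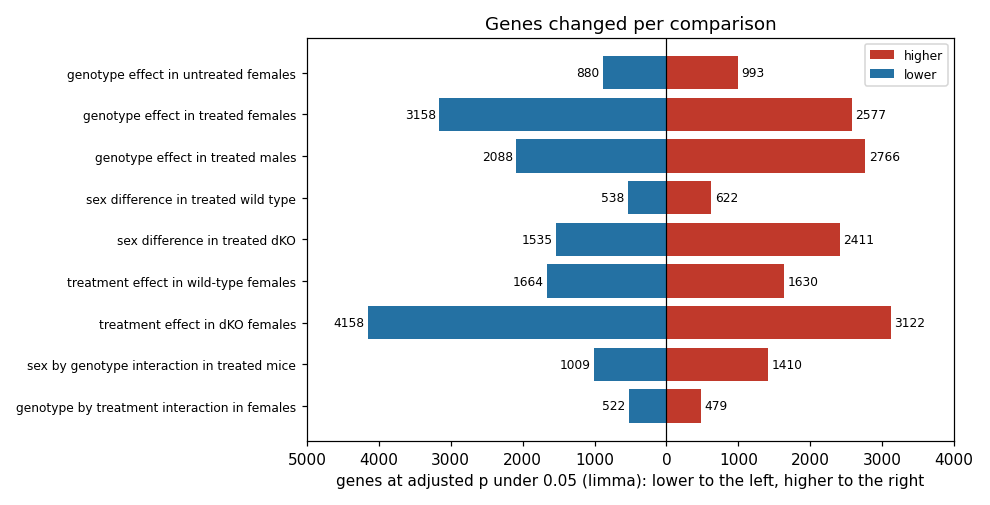
Number of genes called at adjusted p under 0.05 in each comparison, higher in the first-named group to the right and lower to the left (19290 genes tested, n = 4 arrays per group). The effect of treatment in dKO females called the most genes (7280) and the genotype by treatment interaction the fewest (1001).

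The genotype effect itself differed between treated males and females. Of the mitotic genes Cdc20 differed by -4.74 ± 0.64 (male effect minus female effect) and Prc1 by -4.42 ± 0.64. Afp differed by -4.84 ± 0.73, Myc by -1.78 ± 0.35 and the tumour-associated surface protein Ly6d by -7.03 ± 1.11. The glutathione transferase Mgst2 and the carbonyl reductase Cbr3 differed by -6.72 ± 0.75 and -6.16 ± 0.94. The sulfotransferase Sult2a2 went the other way with 5.13 ± 1.18 (largest adjusted p of these 0.00879).

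This interaction called 2419 genes, 1410 positive and 1009 negative. Large positive differences also held Serpina4-ps1 (4.70 ± 0.86), Clec2h (4.32 ± 0.74), Lrrc24 (5.44 ± 1.75), Hamp2 (4.38 ± 1.24), Sult2a4 (5.05 ± 1.24), Slco1a1 (5.36 ± 1.35) and Myh2 (4.26 ± 1.104), and large negative ones Rbp7 (-7.85 ± 1.22), Fam83a (-6.88 ± 0.93), Sdcbp2 (-6.83 ± 1.16), Eps8l3 (-6.38 ± 1.67) and Ckap2 (-6.27 ± 0.92) (largest adjusted p with the genes named next 0.0461). A1bg (positive), Slc7a11 and Npc1l1 (negative) also passed, each with at least 1 group at background on every array. Cyp2b10 (1.07 ± 0.63), Esr1 (0.20 ± 0.34), Foxa3 (0.32 ± 0.39) and Il6 (-0.45 ± 0.58) were not called.

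Of the cell-cycle genes 1 of 37 measured were higher, 29 lower, 7 not called (1 and 34 adjusted over the list alone). Its median was -3.32 (-1.75 with normexp background, camera adjusted p = 4.23e-31, adjusted p = 0.0954 with an estimated correlation). For NRF2 targets 0 of 22 measured were higher, 14 lower, 8 not called (0 and 18 adjusted over the list alone), Abcc4 (-3.62 ± 0.59) and Gsta2 (-3.62 ± 0.97) beside Cbr3. Its median was -1.46 (camera adjusted p = 3.24e-13, adjusted p = 0.221 with an estimated correlation). In the fetal and tumour list 0 of 27 measured were higher, 12 lower, 15 not called (0 and 13 adjusted over the list alone), H19 (-4.77 ± 1.20) beside Afp and Ly6d. Its median was -1.77 (camera adjusted p = 1.35e-08, adjusted p = 0.0954 with an estimated correlation). Of p53 targets 1 of 16 measured were higher, 3 lower, 12 not called (1 and 7 adjusted over the list alone), Phlda3 (-1.94 ± 0.47) among the lower and Perp (0.74 ± 0.24) the one higher. Its median was -0.65 (camera adjusted p = 0.000138, adjusted p = 0.564 with an estimated correlation). Periportal genes were positive, as 7 of 14 measured were higher, 0 lower, 7 not called (11 and 0 adjusted over the list alone), Cyp2f2 (1.61 ± 0.36) and Pigr (1.84 ± 0.43) included. Its median was 1.68 (camera adjusted p = 1.46e-05, adjusted p = 0.564 with an estimated correlation). For female-biased genes 8 of 29 measured were higher, 1 lower, 20 not called (8 and 1 adjusted over the list alone), Slc22a26 (3.96 ± 0.84) beside Sult2a2. Its median was 1.101 (camera adjusted p = 0.00308, adjusted p = 0.642 with an estimated correlation). Without treated dKO female replicate 2 that median was 0.60 and the call was lost.

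Across genes, which are not independent replicates, the genotype effects of the sexes correlated at r = 0.425 in treated mice. Of the called genes 1065 were higher in dKO in both sexes (370 expected if independent) and 826 lower in both (342 expected), while 170 were higher in females and lower in males and 81 the reverse (279 and 453 expected). For sex by genotype calls lost included Eps8l3, H19, Lrrc24 and Perp with slide as a fixed block, Perp and Slco1a1 with normexp background, and Hamp2, Lrrc24 and Perp without some single array. Of 42 called genes followed, the call was lost for 17 with 2 dKO male arrays, 13 with only the groups compared, 9 with slide as a fixed block, 7 with normexp background and 5 with no filter on dim probes. The interaction count was 1694 with slide as a fixed block, 1578 with no filter on dim probes, 1311 with normexp background, 1428 with only these groups in the fit and 1035 without treated dKO male replicates 1 and 4. With 1 array left out it was 1506 to 4442, and median centring gave 694 positive and 1022 negative.

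**Figure D4:**
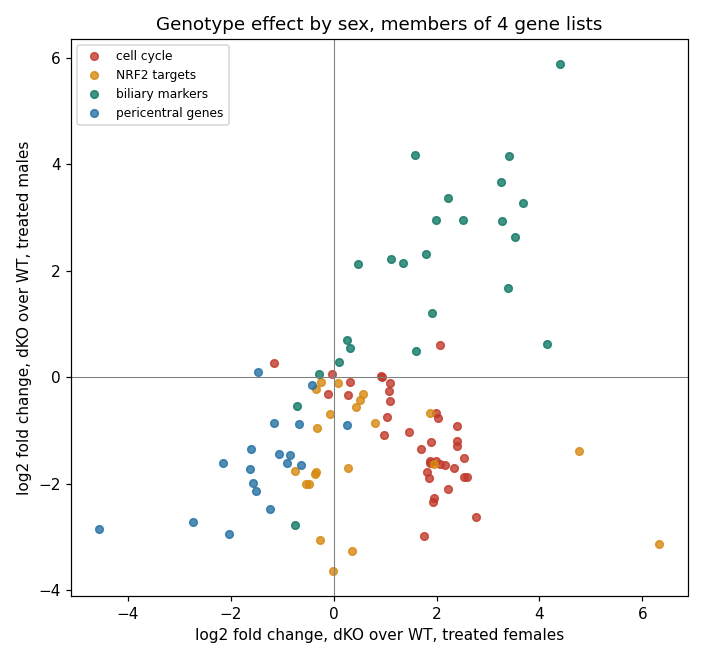
Log2 fold change of dKO over wild type in treated females (x axis) against treated males (y axis), with 1 point per member of the cell-cycle, NRF2 target, biliary and pericentral lists. Cell-cycle genes had a median of 1.87 in females and -1.22 in males, while biliary genes had medians of 1.86 and 2.18.

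Between treated wild-type livers the sexes differed in autosomal and sex-chromosome genes. All directions are male over female, the reverse of the authors' deposited table. Ccnb1 rose by 3.27 ± 0.62 (on 2 of 4 female arrays) and Afp by 2.64 ± 0.52 in males, and the heat shock gene Hspa1b by 4.18 ± 0.39. The male-biased fatty acid hydroxylase Cyp4a12a was higher by 5.67 ± 0.71, and the female-biased homeobox gene Cux2 was at least 38.9-fold lower in males. Xist (chromosome X, 100658920 to 100658979), the RNA of the inactive X and the one gene of its list, was at least 1259-fold lower, and the Y gene Eif2s3y (chromosome Y, 364900 to 364959) at least 166-fold higher (largest adjusted p of these 0.00422).

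This comparison called 1160 genes, 622 higher and 538 lower in males, 309 and 199 by 2-fold or more. Further large rises in males were Ddx3y (at least 86.2-fold higher), Hsd3b5 (5.92 ± 0.99, on 1 of 4 female arrays), Kcnk1 (4.77 ± 0.72, on 1 of 4 female arrays), Moxd1 (at least 8.21-fold higher), Hspa1a (4.55 ± 0.51), Bglap (4.48 ± 0.65, on 3 of 4 female arrays) and Scara5 (4.45 ± 0.75, on 1 of 4 female arrays). Further large falls were A1bg (at least 95.1-fold lower), Sult2a4 (-5.73 ± 0.88), Tsix (at least 8.67-fold lower), Sult2a2 (-4.74 ± 0.83), Hamp2 (-3.67 ± 0.88), Slc22a26 (-3.46 ± 0.60) and Rdh16f2 (-3.23 ± 0.61) (largest adjusted p of these 14 genes 0.0153). The estrogen receptor Esr1 was lower in males (-1.01 ± 0.24, adjusted p = 0.0139). Myc (0.68 ± 0.25), Cyp2b10 (0.05 ± 0.45) and Il6 (-0.69 ± 0.41, on 2 of 4 male arrays and 2 of 4 female arrays) were not called.

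All 4 Y genes of the list were higher in males (4 and 0 adjusted over the list alone), Kdm5d (at least 8.39-fold higher) and Uty (at least 2.78-fold higher) included. Their median was 6.57 (4.75 with dim members at their bound, 2.51 with normexp background, 6.41 to 7.09 within slides, camera adjusted p = 1.17e-19, adjusted p = 0.00226 with an estimated correlation). Of male-biased liver genes 7 of 21 measured were higher, 0 lower, 14 not called (12 and 0 adjusted over the list alone), Cyp4a12b (3.87 ± 0.50) among them. Its median was 0.91 (0.81 to 1.44 within slides, camera adjusted p = 2.79e-12, adjusted p = 0.0195 with an estimated correlation). Of female-biased genes 0 of 29 measured were higher, 9 lower, 20 not called (0 and 14 adjusted over the list alone). Its median was -0.76 (-1.23 with mean of a gene's probes, -0.94 to -0.41 within slides, camera adjusted p = 1.00e-07, adjusted p = 0.249 with an estimated correlation). For the growth hormone axis 0 of 15 measured were higher, 4 lower, 11 not called (0 and 6 adjusted over the list alone), Prlr (-1.75 ± 0.32) and Igf1 (-1.14 ± 0.19) beside Esr1. Its median was -0.39 (-0.66 to 0.21 within slides, camera adjusted p = 4.41e-05, adjusted p = 0.249 with an estimated correlation).

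Cell-cycle genes were higher in wild-type males, as 23 of 37 measured were higher, 1 lower, 13 not called (30 and 1 adjusted over the list alone), Cdk1 (2.68 ± 0.53) and Cdc20 (2.86 ± 0.45) beside Ccnb1. Its median was 1.80 (0.79 with normexp background, 1.35 to 1.71 within slides, camera adjusted p = 1.98e-20, adjusted p = 0.159 with an estimated correlation). The T cell gene Zap70 changed by -1.91 ± 0.24, and among B and plasma cell markers 0 of 11 measured were higher, 6 lower, 5 not called (0 and 7 adjusted over the list alone), Fcmr (-2.26 ± 0.31, on 2 of 4 male arrays) and Ms4a1 (-1.59 ± 0.30) included. Its median was -1.06 (-1.02 with dim members at their bound, -0.38 with no filter on dim probes, -1.68 to -1.12 within slides, camera adjusted p = 2.26e-06, adjusted p = 0.159 with an estimated correlation). For wild-type males and females calls lost included Ccnb1, Cdk1 and Uty with normexp background, and Hamp2 without some single array. Of 51 called genes followed, the call was lost for 8 with normexp background. The count was 1185 with slide as a fixed block, 522 with normexp background and 710 to 1127 with 1 array left out.

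The sexes were also compared between treated dKO livers. Ccnb1 differed by -2.14 ± 0.62 (on 3 of 4 male arrays) and Prc1 by -1.92 ± 0.45. The fetal genes Igf2 and H19 were lower in males (-4.30 ± 0.71 and -3.45 ± 0.85), as was Afp (-2.21 ± 0.52). Slco1a1 was higher in males (5.73 ± 0.95, on 2 of 4 female arrays), as were the major urinary protein Mup3 (4.06 ± 0.48) and the clock gene Per1 (1.70 ± 0.17). The largest adjusted p of these was 0.0196.

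Here 3946 genes were called, 2411 higher and 1535 lower in males, 596 each by 2-fold or more. Large rises also held Eif2s3y (at least 336-fold higher), Ddx3y (at least 168-fold higher), Kdm5d (at least 16.7-fold higher), Uty (at least 5.88-fold higher), Serpina4-ps1 (5.40 ± 0.61), Clec2h (5.16 ± 0.52), Hspa1b (4.15 ± 0.39) and Hspa1a (4.10 ± 0.51). Large falls held Xist (-8.47 ± 0.63, on 2 of 4 male arrays), Tsix (at least 7.22-fold lower), Slc7a11 (at least 25.003-fold lower), Mgst2 (-4.81 ± 0.53), Cux2 (-4.58 ± 0.58, on 3 of 4 male arrays), Meltf (-4.32 ± 0.88, on 2 of 4 male arrays), Akr1c18 (-4.57 ± 1.06, on 2 of 4 male arrays), Tekt5 (at least 10.2-fold lower) and Serpinb9e (at least 15.0-fold lower) (largest adjusted p of these 17 genes 0.00689). Myc was lower in males (-1.104 ± 0.25, adjusted p = 0.00485). Foxa3 (0.83 ± 0.27) and Esr1 (-0.81 ± 0.24) were called (largest adjusted p 0.0360). Cyp2b10 (1.12 ± 0.45) and Il6 (-1.14 ± 0.41, on 1 of 4 male arrays) were not called.

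All 4 Y genes were higher in males (4 and 0 adjusted over the list alone). Their median was 7.69 (5.73 with dim members at their bound, 3.37 with normexp background, 7.66 to 7.69 within slides, camera adjusted p = 6.95e-13, adjusted p = 0.0201 with an estimated correlation). For male-biased liver genes 13 of 21 measured were higher, 1 lower, 7 not called (13 and 1 adjusted over the list alone), Nox4 (3.99 ± 0.44) and Cyp4a12a (3.14 ± 0.71) beside Mup3. Its median was 1.22 (0.57 to 1.19 within slides, camera adjusted p = 2.25e-08, adjusted p = 0.0961 with an estimated correlation). Of the cell-cycle genes 1 of 37 measured were higher, 32 lower, 4 not called (1 and 33 adjusted over the list alone). Its median was -1.48 (-0.97 with normexp background, -1.51 to 0.30 within slides, camera adjusted p = 7.93e-16, adjusted p = 0.254 with an estimated correlation). Without female replicate 2, 16 members were lower and the median was -1.08 (adjusted p = 3.64e-13).

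Interferon response genes were lower in males, as 1 of 25 measured were higher, 9 lower, 15 not called (1 and 10 adjusted over the list alone), Zbp1 (-1.29 ± 0.28) and Ifit1 (-1.58 ± 0.37) included. Its median was -0.72 (-0.88 to -0.39 within slides, camera adjusted p = 1.47e-05, adjusted p = 0.549 with an estimated correlation). Of ER stress genes 6 of 20 measured were higher, 1 lower, 13 not called (11 and 1 adjusted over the list alone), Herpud1 (1.59 ± 0.24) and Creld2 (1.30 ± 0.18) among the higher. Its median was 0.32 (0.21 to 0.35 within slides, camera adjusted p = 0.00502, adjusted p = 0.141 with an estimated correlation). Of circadian genes 7 of 17 measured were higher, 1 lower, 9 not called (10 and 1 adjusted over the list alone), Ciart (2.62 ± 0.45) beside Per1. Its median was 0.65 (0.03 to 0.60 within slides, camera adjusted p = 0.00316, adjusted p = 0.429 with an estimated correlation). Without female replicate 2 that median was 0.37, with the call kept.

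Between the wild-type and dKO sex comparisons the correlation across genes, which are not independent replicates, was r = 0.0117. Of genes called in both, 140 were higher in males and 108 lower in both genotypes (77.7 and 42.8 expected), 144 were higher in wild-type and lower in dKO males and 27 the reverse (49.5 and 67.2 expected). For dKO males and females calls lost included Foxa3 with slide as a fixed block, Ccnb1 with normexp background, and Ccnb1, Esr1 and Foxa3 without some single array. Of 56 called genes followed, the call was lost for 26 with only the groups compared, 19 with 2 dKO male arrays and 6 with 2 dKO female arrays. The count was 2731 with slide as a fixed block, 2285 with normexp background, 1194 with only these 8 arrays in the fit, 1533 without male replicates 1 and 4 and 2341 to 6064 with 1 array left out, and median centring gave 1514 higher and 1558 lower.

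**Figure D5:**
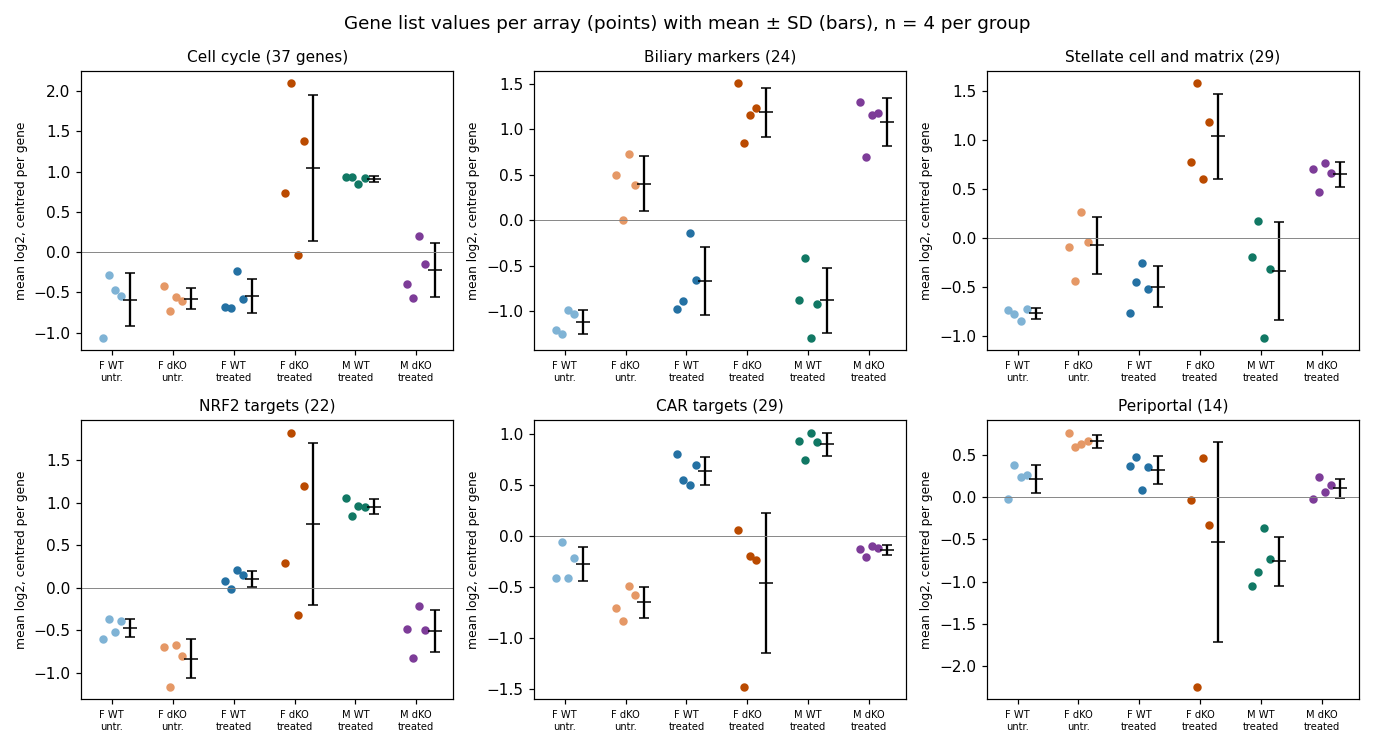
Mean of the members' log2 signals, each centred on its mean over the 24 arrays, for 6 gene lists, with 1 point per array and bars for the group mean ± SD (n = 4). The mean of the cell-cycle list was highest in treated dKO females (replicate 3 at -0.03, others 0.74 to 2.10) and treated wild-type males, and the biliary list lay higher in each dKO group than in its wild-type counterpart.

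In wild-type females, DEN and TCPOBOP changed genes of several kinds. Cyp2b10 (chromosome 7, 26702056 to 26702115) rose by 3.09 ± 0.45 and Cyp2c55, another cytochrome P450 induced through CAR, by 5.41 ± 0.61. The pancreatic lipase relative Pnliprp1 rose by 10.29 ± 0.66 (on 1 of 4 untreated arrays), Sult1e1 by 7.60 ± 0.67 and the neutrophil alarmin S100a8 by 7.10 ± 1.12 (on 2 of 4 untreated arrays). The chemokine Cxcl10 and the guanylate-binding protein Gbp2, both interferon-induced, rose by 3.44 ± 0.79 and 2.28 ± 0.45. The fatty acid hydroxylase Cyp4a14 changed by -3.17 ± 0.57 (largest adjusted p of these 0.00603).

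In all 3294 genes were called, 1630 higher and 1664 lower after treatment, 901 and 378 by 2-fold or more. Further large rises were Tmeff2 (at least 113-fold higher), Ptges (at least 51.3-fold higher), Nebl (at least 26.1-fold higher), Elapor1 (6.30 ± 0.40, on 3 of 4 untreated arrays), Tff3 (at least 11.6-fold higher) and Chil1 (5.54 ± 1.04, on 1 of 4 untreated arrays). Large falls were Prom2 (at least 14.4-fold lower), Nlrp12 (-5.55 ± 1.04, on 3 of 4 treated arrays), Hsd3b5 (-5.18 ± 0.99, on 1 of 4 treated arrays), Ifi44l (at least 5.92-fold lower), Unc79 (-4.63 ± 0.63, on 3 of 4 treated arrays), Gdpd3 (-4.54 ± 1.04, on 1 of 4 treated arrays), Extl1 (-4.43 ± 0.38, on 2 of 4 treated arrays), Krt23 (-4.35 ± 0.34), Susd4 (-3.98 ± 0.38) and Mme (-3.97 ± 0.74, on 3 of 4 treated arrays) (largest adjusted p of these 16 genes 0.00597). Esr1 (-0.91 ± 0.24, adjusted p = 0.0130) and Foxa1 (-0.85 ± 0.28, adjusted p = 0.0395) were lower. Il6 was higher (1.51 ± 0.41, on 2 of 4 treated arrays and 1 of 4 untreated arrays, adjusted p = 0.0159). Afp (1.44 ± 0.52), Myc (-0.02 ± 0.25) and Foxa3 (-0.10 ± 0.27) were not called.

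Of CAR targets 9 of 29 measured were higher, 1 lower, 19 not called (10 and 1 adjusted over the list alone), Akr1b7 (4.54 ± 0.56) and Abcc4 (2.34 ± 0.42) included. Its median was 0.57 (0.53 to 0.76 within slides, camera adjusted p = 6.12e-06, adjusted p = 0.312 with an estimated correlation). Of interferon response genes 19 of 25 measured were higher, 0 lower, 6 not called (23 and 0 adjusted over the list alone). Its median was 1.48 (0.57 to 1.49 within slides, camera adjusted p = 5.33e-15, adjusted p = 0.264 with an estimated correlation). In the acute phase list 13 of 29 measured were higher, 2 lower, 14 not called (14 and 3 adjusted over the list alone), the serum amyloids Saa1 (2.90 ± 0.69) and Saa2 (2.89 ± 0.68) included. Its median was 0.48 (0.86 with slide as a fixed block, -0.000368 to 0.59 within slides, camera adjusted p = 0.000625, adjusted p = 0.542 with an estimated correlation).

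For macrophages 11 of 20 measured were higher, 0 lower, 9 not called (16 and 0 adjusted over the list alone), Lyz2 (1.72 ± 0.43) and Lyz1 (1.86 ± 0.46) included. Its median was 1.30 (1.24 with dim members at their bound, 0.98 to 1.71 within slides, camera adjusted p = 5.84e-09, adjusted p = 0.270 with an estimated correlation). For T and NK cells 8 of 18 measured were higher, 1 lower, 9 not called (12 and 1 adjusted over the list alone), Lck (1.45 ± 0.36) and Gzmb (1.61 ± 0.38) included. Its median was 0.93 (0.16 to 1.01 within slides, camera adjusted p = 4.69e-06, adjusted p = 0.328 with an estimated correlation). For neutrophils 3 of 12 measured were higher, 0 lower, 9 not called (5 and 0 adjusted over the list alone), S100a8 and S100a9 (1.88 ± 0.63) and Cxcr2, which was at background on every untreated array. Its median was 0.97 (0.61 with dim members at their bound, 0.50 with normexp background, 0.15 to 1.19 within slides, camera adjusted p = 0.00186, adjusted p = 0.441 with an estimated correlation). For endothelium 3 of 20 measured were higher, 0 lower, 17 not called (3 and 0 adjusted over the list alone), Cd34 (1.43 ± 0.25) and Lyve1 (1.49 ± 0.44) included. Its median was 0.32 (0.20 without treated wild-type female replicate 2, 0.39 to 0.70 within slides, camera adjusted p = 0.000212, adjusted p = 0.441 with an estimated correlation). For treated wild-type females calls lost included Foxa1 and Lyve1 with slide as a fixed block, Foxa1, Gdpd3, Ifi44l, Il6 and S100a9 with normexp background, and Foxa1, Il6, Lyve1 and S100a9 without some single array. Of 58 called genes followed, the call was lost for 14 with normexp background, 12 with only the groups compared, 9 with slide as a fixed block and 6 with no filter on dim probes. The count was 2478 with slide as a fixed block, 1882 with normexp background (median of all genes 0.09 instead of -0.06) and 1946 without treated replicate 3, and median centring gave 1257 higher and 2268 lower.

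In dKO females treatment changed more genes than in wild-type females, but with array position as a covariate the counts were 2391 and 2561. Cyp2b10 did not pass the test (0.43 ± 0.45, adjusted p = 0.477), but without treated replicate 2 its rise was 1.18 and passed. Ccnb1 was at least 5.67-fold higher and Col1a1 rose by 2.98 ± 0.43. The imprinted fetal genes Igf2 (chromosome 7, 149836673 to 149836709) and H19 (chromosome 7, 149761769 to 149761828) rose by 6.05 ± 0.71 and 6.46 ± 0.85 (on 3 of 4 untreated arrays), Cbr3 by 5.51 ± 0.66 and Afp by 2.62 ± 0.52. Slc1a2 changed by -3.89 ± 0.57, Cyp4a14 by -5.73 ± 0.57 and the iron hormone Hamp by -3.92 ± 0.62 (largest adjusted p of these 0.000778). The Afp rise came mainly from treated replicates 2 and 4.

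This comparison called 7280 genes, 3122 higher and 4158 lower, 1644 and 997 by 2-fold or more. Further large rises were Slc7a11 (at least 22.2-fold higher), Mgst2 (6.34 ± 0.53), Ptges (6.20 ± 0.52, on 1 of 4 untreated arrays), Trim12a (5.74 ± 1.36, on 2 of 4 untreated arrays), Ubd (5.72 ± 1.01), Serpina7 (5.71 ± 0.65) and Nebl (at least 13.4-fold higher). Further large falls were Ifi44l (at least 15.5-fold lower), A1bg (-5.64 ± 1.07), Lrrc19 (-4.99 ± 0.68, on 1 of 4 treated arrays), Qdpr (-4.73 ± 0.97), Htra4 (-4.66 ± 0.53, on 1 of 4 treated arrays), Sucnr1 (-4.49 ± 0.53), Gbp2b (-4.46 ± 0.48) and Myh2 (-4.31 ± 0.78, on 3 of 4 treated arrays) (largest adjusted p of these 15 genes 0.00283). Myc was higher (1.03 ± 0.25), and Esr1 (-1.71 ± 0.24) was lower (largest adjusted p 0.00335). Il6 was higher (1.06 ± 0.41, on 1 of 4 untreated arrays, adjusted p = 0.0471) and residual Foxa2, mostly near background, was called lower (-2.07 ± 0.77, on 2 of 4 treated arrays and 3 of 4 untreated arrays, adjusted p = 0.0394). Foxa3 (-0.30 ± 0.27) was not called.

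Of the cell-cycle genes 27 of 37 measured were higher, 2 lower, 8 not called (29 and 2 adjusted over the list alone), Rrm2 (3.02 ± 0.50, on 3 of 4 untreated arrays) and Prc1 (3.31 ± 0.45) beside Ccnb1. Its median was 2.004 (1.77 with dim members at their bound, 0.99 with filter on all 24 arrays, 1.254 to 3.34 within slides, camera adjusted p = 1.44e-10, adjusted p = 0.447 with an estimated correlation). For stellate cell, fibroblast and matrix genes 20 of 29 measured were higher, 1 lower, 8 not called (22 and 1 adjusted over the list alone), Mmp2 (2.03 ± 0.32) and Col4a1 (2.42 ± 0.46) included. Its median was 1.26 (0.99 with dim members at their bound, 0.83 with normexp background, 0.97 to 1.55 within slides, camera adjusted p = 2.41e-08, adjusted p = 0.447 with an estimated correlation). Of NRF2 targets 15 of 22 measured were higher, 0 lower, 7 not called (19 and 0 adjusted over the list alone), Srxn1 (2.80 ± 0.48) and Abcc4 (3.07 ± 0.42) beside Cbr3. Its median was 0.999 (0.87 to 1.88 within slides, camera adjusted p = 2.41e-08, adjusted p = 0.447 with an estimated correlation). CAR targets were divided, as 11 of 29 measured were higher, 7 lower, 11 not called (11 and 7 adjusted over the list alone), Cyp2c55 (2.75 ± 0.61) and Akr1b7 (2.51 ± 0.56) among the higher. Its median was -0.10 (mean 0.19, -1.14 to 0.67 within slides, camera adjusted p = 0.384, adjusted p = 0.834 with an estimated correlation). Without treated replicate 2 that median was 0.43 and called higher (adjusted p = 0.0366).

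Of pericentral genes 0 of 18 measured were higher, 15 lower, 3 not called (1 and 15 adjusted over the list alone), Slc22a3 (at least 5.58-fold lower, on 3 of 4 untreated arrays) beside Slc1a2. Its median was -1.23 (-2.95 to -0.68 within slides, camera adjusted p = 0.000191, adjusted p = 0.447 with an estimated correlation). Of periportal genes 0 of 14 measured were higher, 9 lower, 5 not called (0 and 10 adjusted over the list alone), Ass1 (-1.68 ± 0.41) and Gls2 (-2.02 ± 0.57) included. Its median was -1.18 (-2.40 to -0.87 within slides, camera adjusted p = 0.000998, adjusted p = 0.447 with an estimated correlation). Without treated replicate 2 the medians were -0.74 (pericentral) and -0.67 (periportal).

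Across genes, which are not independent replicates, the treatment effects in wild-type and dKO females correlated at r = 0.525, with 869 genes higher and 1008 lower after treatment in both (264 and 359 expected if independent). For treated dKO females calls lost included Foxa2 with slide as a fixed block, Il6 with normexp background, and Foxa2 and Il6 without some single array. Of 67 called genes followed, the call was lost for 25 with array position as a covariate and 16 with only the groups compared. The count was 7723 with slide as a fixed block, 2391 with array position as a covariate and 4461 with only these 8 arrays in the fit.

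The effect of treatment differed between dKO and wild-type females for a smaller set of genes. The rise of Cyp2b10 was smaller in dKO by a difference of -2.66 ± 0.63 (adjusted p = 0.0201). Pnliprp1 differed by -9.68 ± 0.94 and Sult1e1 by -8.58 ± 0.95. In the other direction the hormone Fgf21 differed by 6.71 ± 1.20, the thyroxine-binding globulin Serpina7 by 6.44 ± 0.92 and the DNA repair gene Rad51b by 4.83 ± 0.81 (largest adjusted p of these 0.00503).

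The test called 1001 genes, 479 positive and 522 negative. Other large differences were Rgs8 (5.11 ± 0.998) and Cela1 (5.02 ± 0.97) on the positive side and Cfd (-10.18 ± 1.996), Gbp2b (-4.72 ± 0.69), Lrrc19 (-4.78 ± 0.97) and Cyp4a12a (-4.20 ± 1.0002) on the negative side (largest adjusted p with the genes named next 0.0499). Prnd, Hsd3b5, Tekt5, Ypel4 and Slc7a11 (positive) and Tmeff2, Ankrd22, Duoxa1 and Erich5 (negative) also passed, each with at least 1 group at background on every array. Afp (1.18 ± 0.73), Myc (1.06 ± 0.35), Esr1 (-0.81 ± 0.34), Foxa3 (-0.20 ± 0.39) and Il6 (-0.45 ± 0.58) were not called.

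Of the cell-cycle genes 11 of 37 measured were higher, 0 lower, 26 not called (31 and 1 adjusted over the list alone), Mcm6 (2.43 ± 0.56) and Prc1 (2.63 ± 0.64) included. Its median was 1.78 (0.95 with normexp background, camera adjusted p = 1.42e-15, adjusted p = 0.574 with an estimated correlation). For stellate cell, fibroblast and matrix genes 6 of 29 measured were higher, 0 lower, 23 not called (10 and 0 adjusted over the list alone), Ccn2 (1.89 ± 0.27) and Lum (1.47 ± 0.30) included. Its median was 0.91 (camera adjusted p = 1.15e-06, adjusted p = 0.574 with an estimated correlation). Of CAR targets 0 of 29 measured were higher, 4 lower, 25 not called (0 and 7 adjusted over the list alone), Gstt3 (-1.86 ± 0.34) beside Cyp2b10. Its median was -0.56 (-0.91 without treated dKO female replicate 1, camera adjusted p = 0.00211, adjusted p = 0.574 with an estimated correlation). Normexp background ended that call, and without dKO treated replicate 2 the median was -0.23, with the call kept. For genotype by treatment calls lost included Cela1, Cyp4a12a, Prc1 and Rgs8 with normexp background, and Prc1 without some single array. Of 37 called genes followed, the call was lost for 34 with array position as a covariate, 19 with normexp background, 14 with only the groups compared, 8 with no filter on dim probes, 5 with replicate block and 4 with 2 dKO female arrays. The count was 1493 with slide as a fixed block, 6 with array position as a covariate, 561 with no filter on dim probes (median of all genes -0.18 instead of -0.02), 421 with normexp background and 488 with only these groups in the fit. With 1 array left out it was 460 to 2414.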

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

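The tests of lower scaled background and of leukocytes were chosen after the result was seen. Of 264 groups of 4 values examined, 7 held a value far from the other 3, and chance flags about 1 in 20 groups. These were, as mean log2 of a list on 1 array, female-biased genes in treated wild-type female replicate 3 (0.167, others 0.918 to 1.01), bile acid genes in treated dKO female replicate 2 (-1.47, others -0.443 to -0.232) and B and plasma cell markers in treated wild-type male replicate 3 (-1.27, others -0.369 to -0.189). The others were erythroid genes in untreated dKO female replicate 2 (-0.408, others 0.114 to 0.166), pancreas genes in treated wild-type female replicate 3 (0.408, others 0.677 to 0.709), ER stress genes in treated wild-type male replicate 2 (0.0353, others 0.220 to 0.255) and Il6 in treated dKO female replicate 3 (-5.39, others -4.67 to -4.56).

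The genotype effect differed between treated males and females (2419 genes), for Afp (-4.84) and Myc (-1.78). By list median it differed for female-biased genes (1.101), the growth hormone axis (0.81), the cell cycle (-3.32), fetal and tumour genes (-1.77), periportal genes (1.68), p53 targets (-0.65) and NRF2 targets (-1.46), the list calls all lost with an estimated correlation (adjusted p = 0.0954 to 0.642). The treatment effect differed between dKO and wild-type females (1001 genes), for Cyp2b10 (-2.66) and by list median for female-biased genes (-1.31), CAR targets (-0.56), the cell cycle (1.78), matrix genes (0.91), pericentral genes (-1.22) and periportal genes (-1.21), the list calls all lost with an estimated correlation (adjusted p = 0.574). Without treated dKO female replicate 2 the medians were -0.53 (female-biased), -0.23 (CAR targets), -0.58 (pericentral) and -0.52 (periportal), and 0.60 with the call lost for female-biased genes by sex and genotype.

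Regrouping the arrays tested whether chance could give as many called genes. For each group comparison the real split called the most of 35: 1873 against at most 11 in untreated females by genotype, 5735 against 4826 in treated females, 4854 against 10 in treated males, 1160 against 181 for sex in wild type, 3946 against 1422 for sex in dKO, 3294 against 8 for treatment in wild type and 7280 against 3031 for treatment in dKO. The split with 4826 exchanged replicate 3 of treated dKO and treated wild-type females, which points to a structure among those samples. Of 100 regroupings, 3 including the real one called as many as sex by genotype (2419, highest other 3054). Only the real one called as many as genotype by treatment (1001, highest other 660). Here regrouping mixed the main effects too, so it cannot tell if chance gives such interactions.

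Treated dKO male replicates 1 and 4 held Xist above background, at 1.096% and 0.403% of its mean in treated wild-type females. Foxa2 was at 0.873% and 0.502% there, and both were at background in replicates 2 and 3. If replicate 4 pools replicates 1 to 3, its trace may come from replicate 1. A small share of wild-type female RNA would raise both genes. Only 1 informative gene could be tested (100% at the predicted level), so the test cannot tell. The minimum of 3 was set after only 1 was found. No biological explanation was tested.

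The genotype effect in treated mice could follow the position of arrays on their slides, since few calls were left with position as a covariate, and no biological explanation was tested. The slope with position within groups carried 0.118 of the called genes' fold changes in females (SE 0.127) and 0.0894 in males (SE 0.0590), which argues against a linear trend with position as the main source. Treated dKO females all sat at position 4 and treated wild-type males all at position 1, so the slope came from the other groups, and an effect of those positions alone cannot be told apart from group. The covariate made the standard errors in females 2.17 times as large, while fold changes with and without it correlated at r = 0.939 in females and 0.942 in males. Lower scaled background of the brighter dKO female arrays fits the 50 genes at background in both groups (median -0.663, SE 0.0879, against -0.07 for all genes; 8 called, all lower), and for brighter genes it was not tested. Such dim genes also shifted for treatment in dKO females (median -0.95, 13 of 55 called, all lower) and sex in dKO (0.71, 4 of 71 called, all higher), so calls near background there, residual Foxa2 included, may share this shift.

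Cell-cycle genes were higher in treated dKO females than in treated dKO males, and a single array may add to this. Without treated dKO female replicate 2, 16 members were called lower in males instead of 32, so the count rests partly on that array, while the median moved from -1.48 to -1.08 and stayed called (adjusted p = 3.64e-13). The list averaged 2.10 and 1.38 on female replicates 2 and 4, 0.74 and -0.03 on 1 and 3, and -0.58 to 0.20 on the male arrays. If replicate 4 holds replicate 2, leaving out 1 array cannot tell whether 1 sample carries the difference. With array position as a covariate 29 members were called, which argues against position. More leukocytes in the female samples would raise their markers alike, but these had a median of -0.228 (SE 0.0961, 61 genes) against -1.48 for the cell cycle. No biological explanation was tested.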

How the results depend on the processing

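The 3 added alternatives were chosen after the data were seen. Of 12193 alternative values for 534 named-gene results, 11192 kept direction and threshold side, 944 lost the call, 24 gained it and 33 changed sign. None of these 33 was called in the main result. Foxa1 was at background on every dKO array, so its interaction values below reflect background and give no size or sign. Over the lists, 1907 values for 98 results gave 1878 unchanged in direction and call (medians that moved over 1.5 times stand beside the result), 16 lost and 13 reversed, and with slide as a fixed block 97 of the 98 list results were unchanged, called or not. These list calls used camera's preset correlation of 0.01. The estimated correlation was not counted among these alternatives, and with it most of the list calls described above were lost. A replicate block, with arrays of the same replicate number paired, left every count of called genes within 1.5 times. The pairing was not borne out by the arrays (r -0.341 to 0.318). Signal over background limited the dim genes.

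With array position covariate, calls numbered 6 (genotype by treatment), 43 and 202 (genotype in treated females and males) and 2391 (treatment in dKO females). Values changed sign for Foxa1 0.63 (genotype by treatment), and Foxa3 -0.18 and PPARA targets 0.0109 (genotype in treated females and males, respectively). They also did for Foxa3 0.14 and CAR targets 0.0614 (treatment in wild-type and dKO females, respectively). For genotype in untreated females Myc 0.0765 and cell cycle 0.00486 did so. With filter on all 24 arrays, values changed sign for cell cycle 0.0133 (genotype in untreated females). With mean of a gene's probes, values changed sign for Esr1 -0.0341 (sex by genotype) and cell cycle 0.0212 (genotype in untreated females). With no filter on dim probes, calls numbered 561 (genotype by treatment) and 1578 (sex by genotype). With normexp background, calls numbered 421 (genotype by treatment), 1311 (sex by genotype) and 1882 (treatment in wild-type females). They were 2552 and 730 (genotype in treated males and untreated females), and 2285 and 522 (sex in treated dKO and wild type). Values changed sign for Foxa1 0.0490 (genotype by treatment) and Il6 -0.16 (genotype in untreated females). So did Il6 0.39 (sex by genotype) and Il6 0.0380 (sex in treated dKO). With only the groups compared, calls numbered 488 (genotype by treatment) and 1428 (sex by genotype). By genotype they were 2128 (treated females) and 2812 (untreated females), by sex 1194 (treated dKO) and by treatment 4461 (dKO females). With quantile normalization, values changed sign for Foxa1 0.82 (genotype by treatment) and Foxa1 -0.52 (sex by genotype). So did CAR targets 0.12 (treatment in dKO females) and cell cycle 0.000655 (genotype in untreated females). With slide as a fixed block, calls numbered 1189 (genotype in untreated females) and values changed sign for Cyp2b10 -0.0458 (sex in treated wild type). Without treated dKO female replicates 2 and 3, values changed sign for CAR targets 0.47 (treatment in dKO females). Without treated dKO male replicates 1 and 4, calls numbered 2676 (genotype in treated males), 1035 (sex by genotype) and 1533 (sex in treated dKO). The cause was not tested, except that fewer arrays and arrays chosen for their distance change the spread by construction.

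With each array left out in turn, calls numbered 460 to 2414 (genotype by treatment) and 1506 to 4442 (sex by genotype). By genotype they were 3950 to 7270 (treated females), 3860 to 4706 (treated males) and 1121 to 1774 (untreated females). By sex they were 2341 to 6064 (treated dKO) and 710 to 1127 (treated wild type). By treatment they were 5600 to 8408 (dKO females) and 1946 to 3017 (wild-type females). Some values changed sign. For genotype in treated females the ranges were Esr1 -0.54 to 0.0501 and Il6 -0.46 to 0.15. In untreated females they were Myc -0.25 to 0.17 and cell cycle -0.19 to 0.10. For treatment in wild-type females they were Foxa3 -0.30 to 0.0431 and Myc -0.26 to 0.17. In dKO females they were Cyp2b10 -0.00368 to 1.18 and CAR targets -0.20 to 0.43. For sex in treated wild type the range was Cyp2b10 -0.0784 to 0.19, and for sex by genotype Esr1 -0.13 to 0.46. For genotype by treatment they were Foxa1 -0.43 to 0.18 and Foxa3 -0.47 to 0.0696. None of these was called in the main result, and the cause was not tested.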

Other observations

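No further test was chosen after the results were seen for this part. In wild-type females Cyp2b10 averaged 2.51 ± 0.10 untreated (SD, log2 relative to the 75th percentile) and 5.61 ± 0.37 treated. The dKO females averaged 3.69 ± 0.18 untreated, a genotype difference that was not called, and 4.12 ± 1.54 treated, where replicate 2 lay at 1.88 and the others at 4.48 to 5.42. Afp averaged -0.42 ± 0.16 in treated wild-type and 0.31 ± 1.64 in treated dKO females.

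Across genes, which are not independent replicates, genotype effects in untreated females correlated with those in treated females (r = 0.482) and treated males (r = 0.412). Of the called genes 609 were higher in dKO in untreated and treated females (133 expected if independent) and 429 lower (144 expected), and 548 and 334 in untreated females and treated males (142 and 95.3 expected).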
